A study of Homo sapiens with 9 samples.

How the data were processed

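Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out in 3 lung adenocarcinoma cell lines, NCI-H3122, NCI-H1819 and NCI-H2087, which carry an amplification of NKX2-1 per the labels. Cells were fixed with formaldehyde and the chromatin was sheared by sonication, per the labels' protocols. NKX2-1 was precipitated with an antibody from Bethyl Laboratories in each line, and FOXA1 with an antibody from Abcam in H3122. Of the 9 samples, 5 were precipitated libraries with 1 peak list each and were analysed here. The other 4 were input libraries, which were not analysed here, and the sources used here do not state which input served as the control for which list. H3122 had 2 NKX2-1 lists, called replicates 1 and 2 here; the label of the second carries the number 2. Nothing in the labels says that they came from separate cultures, so their difference may be technical.

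Reads were aligned with Bowtie to the human genome build hg18 and peaks were called with MACS 1.4.0, per the submitters' processing notes. Each deposited list gave a peak's position and a score, and peaks were called on single libraries per the labels, which tie each list to 1 library. The deposited score is the authors' own value for each peak. It was read as 10 times the negative log10 of the peak's p-value, the scale MACS uses, since the lowest scores lay at the value of a round p; no source used here states the scale. The lowest score was 50 in H3122 NKX2-1 replicate 1, the score of a p of 1e-05, and 60 in the other lists, the score of a p of 1e-06. Read in this way, replicate 1 held peaks down to a higher p than the other lists; the thresholds used for calling are not given in the sources used here. Scores piled up at 3100 in the other lists, where the calculation saturates. Scores were used only to rank or select peaks within a list. Read counts and depth are not given in the sources used here, so differences in the number of peaks cannot be set against depth.

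Peaks were counted as shared where they overlapped by at least 1 bp. Shares were computed in both directions with Wilson 95% intervals, which cover counting error only, since peaks are not replicates. Chance was estimated from 1000 circular shifts of one list along each chromosome, which keep peak widths and spacing. All NKX2-1 peaks were also merged where they overlapped, and each merged region was classed by the lists with a peak in it. H3122 counted as occupied where both of its replicates had a peak. The share of regions with a FOXA1 peak was compared between classes by a two-sided Fisher's exact test over regions with a Newcombe interval of the difference. Matched comparisons used the Cochran-Mantel-Haenszel test over strata. These p-values describe regions of these lists and not replicate cultures.

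Peak density was computed in windows of 1 Mb relative to the mean of the list. Density was also computed in cytogenetic bands and in classes of Giemsa stain, the latter over autosomes, with intervals of the ratio of light to dark bands from 1000 bootstrap draws over chromosomes. The lengths of the hg18 chromosomes came from GenomeInfoDb 1.38.1 and the bands from circlize 0.4.16, run in R 4.3.3. Bands were ranked among the 755 of at least 1 Mb. Other computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9. Peaks on unplaced sequence were counted but left out of overlaps.

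The overlap code was tested on simulated lists with planted sharing. A planted share of 60.3% over the 7469 peaks of replicate 1 was recovered as 60.4%. A planted 20.2% over 13483 H1819 peaks came back as 20.8%, and 50.1% over 42429 FOXA1 peaks as 50.9%; random overlaps add to the planted ones.

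The regions named in the text followed a rule fixed before the data were examined. It took the 10 regions in all 4 NKX2-1 lists with the highest mean rank of score within the lists. It took the 5 highest-scoring regions found only in H1819, only in H2087 or only in both H3122 replicates. Where a set drew on more than 1 list, regions were ordered by mean rank, and scores of exactly 3100 are tied. Scores above 3100, up to 3217, ranked higher although the calculation saturates there. The order among such peaks therefore says little about their strength. The rule also took the 5 highest regions shared by NKX2-1 replicate 2 and FOXA1, and the 5 highest in both H3122 NKX2-1 replicates without FOXA1. The 5 highest FOXA1 peaks without an H3122 NKX2-1 peak, the 5 densest windows of each list and band 14q13 were taken as well. A subset of these is named. Alternatives changed the score threshold, the overlap rule, the chance model, list lengths, merging, the lists standing for H3122, the windows and the chromosomes used. Comparisons by Giemsa stain, by gene band, by region or peak width and with 1 other cell line at a time were chosen after the data were seen. Gene annotation and sequence of hg18 were not used here. Planned counts of genes near peaks, tests of fixed gene lists and motif searches were therefore not run, and the text does not say whether a region is exonic, intronic or intergenic.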

Results

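NKX2-1, also called TTF-1, is a homeodomain transcription factor of lung and thyroid development whose gene is amplified in a subset of lung adenocarcinomas. Its occupancy was mapped by ChIP-seq in 3 lung adenocarcinoma cell lines with this amplification, with 2 lists from H3122 and 1 each from H1819 and H2087. FOXA1, a forkhead pioneer factor of endodermal tissues, was mapped in H3122 with 1 list. Apart from the H3122 NKX2-1 pair there were no replicates. The lists held 7469 NKX2-1 peaks in H3122 replicate 1, 48071 in H3122 replicate 2, 13486 in H1819 and 14441 in H2087, and 42437 FOXA1 peaks in H3122. Median peak widths were 314, 656, 479, 592 and 569 bp in that order. The peaks covered 2.56, 34.4, 7.02, 9.97 and 25.6 Mb. Read depth is not known for any list, so the number of peaks cannot be compared between lines as an amount of binding. The 2 H3122 lists alone differed 6.44-fold in number, and 17.8-fold at scores of at least 100.

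The agreement of the H3122 replicates sets the scale for every other comparison. The short list was largely contained in the long one: 6103 of 7469 replicate 1 peaks overlapped a replicate 2 peak, a share of 81.7% (95% Wilson interval 80.8 to 82.6). Circular shifts gave 1.74% on average and at most 2.36%, so the overlap was 46.9-fold above chance. In the lowest decile of replicate 1 scores 70.8% of peaks were shared, against 98.9% in the highest decile. Replicate 2 peaks were found in replicate 1 in only 12.5% of cases (12.2 to 12.8). That share rose from 1.62% in the lowest decile of replicate 2 scores to 54.4% in the highest. Replicate 2 peaks shared with replicate 1 had a median score of 454 and the remaining peaks one of 124.0. When the 7469 best peaks of each list were compared, the share of replicate 1 peaks found in replicate 2 was 46.3% (45.1 to 47.4).

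NKX2-1 occupancy overlapped between the lines far above chance. With lists of equal length it overlapped less between lines than between the H3122 replicates, while the lists as deposited, which differ in length, gave no single order. Of the H1819 peaks, 53.4% (52.5 to 54.2) overlapped the long H3122 list, 26.6-fold above chance. Of the H2087 peaks, 67.7% (66.9 to 68.4) did, 29.6-fold above chance. H1819 and H2087 shared 22.8% (22.1 to 23.6) of H1819 peaks and 21.0% (20.3 to 21.6) of H2087 peaks, 38.1- and 37.4-fold above chance. With 7469 best peaks per list, the shares between lines ran from 17.5% to 28.6%, all below the 45.0% and 46.3% between the H3122 replicates. Only 1 replicate pair exists, so this difference has no test over replicates. As deposited, replicate 1 overlapped H1819 63.5-fold and H2087 56.6-fold above chance, both over the 46.9-fold between the replicates. These folds cannot be ranked against each other, because the largest possible fold falls as chance rises with list length. Chance was 1.74% for the long replicate 2 list, 0.40% for H1819 and 0.53% for H2087. Replicate 2 peaks were found in 14.7% of cases in H1819 and 20.01% in H2087, against 12.5% in the short replicate 1. The share of H2087 peaks found in H3122 replicate 2 rose with score, from 48.5% in the lowest decile to 87.0% in the highest. For H1819 peaks it rose from 46.0% to 63.3%. The share of H1819 peaks found in H2087 was 20.2% in the lowest decile (18.2 to 22.5) and 21.4% in the highest (19.3 to 23.7), a difference within the counting intervals. It was higher in between, at 25.8% (23.55 to 28.2) in decile 7. In the other direction the share rose with score, and H2087 peaks were found in H1819 in 9.77% of cases in the lowest decile and 34.2% in the highest. The fold above chance depended on the chance model, and for H1819 peaks in H2087 it fell to 24.98 when peaks were shifted by 20 to 500 kb only.

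**Figure D1:**
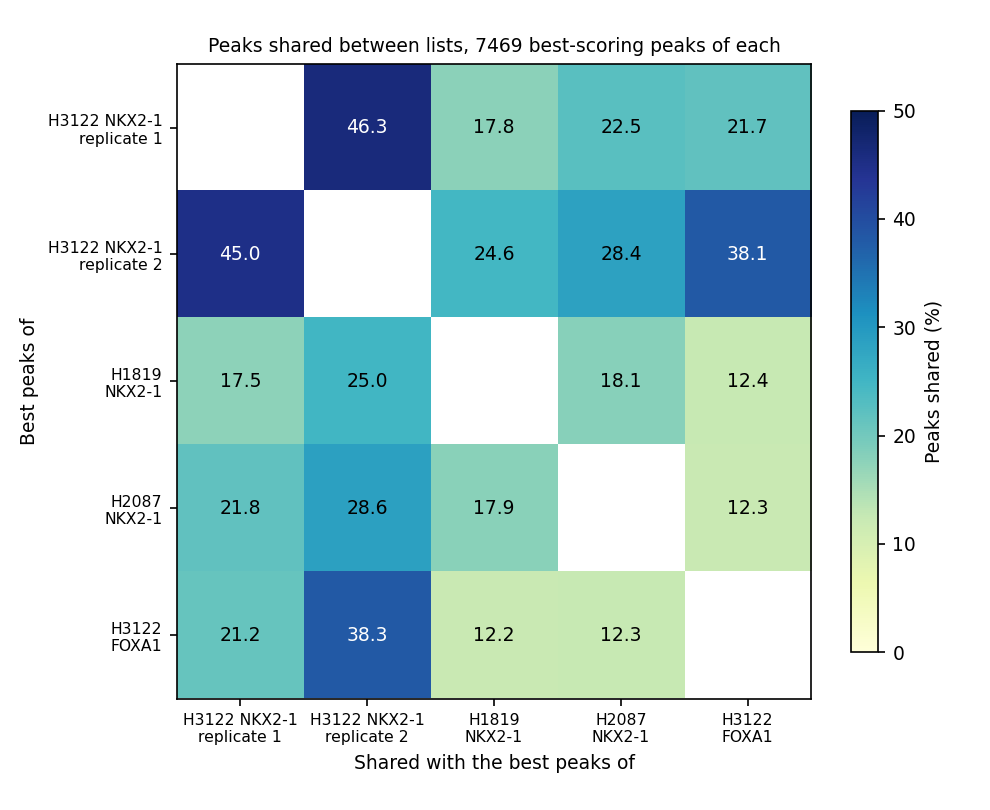
Share of peaks (%) of the list on the vertical axis that overlapped a peak of the list on the horizontal axis by at least 1 bp, with the 7469 best-scoring peaks of each list; colour shows the same value. The H3122 NKX2-1 replicates shared 46.3% and 45.0%, and NKX2-1 replicate 2 and FOXA1 shared 38.1% and 38.3%.

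A core of 962 merged regions held NKX2-1 peaks in all 3 lines and both H3122 replicates. Independent shifts of the H1819 and H2087 lists, with both H3122 lists left in place, gave 0.481 such regions on average and at most 4. Of the 5972 regions in both H3122 replicates, 31.5% were also in H1819, 35.9% in H2087 and 16.1% in both. If the H1819 and H2087 overlaps were independent within these regions, 675 would be expected in both; the observed number was 1.43 times that. A further 920 regions were shared with H1819 alone, 1179 with H2087 alone, and 2911 were seen in both H3122 replicates and no other line. The H1819 list alone held 5972 regions and the H2087 list alone 4342. The core depended on which H3122 lists were required: replicate 2 alone gave 2742 regions, and scores of at least 100 in every list gave 290.

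The region that ranked highest across all 4 NKX2-1 lists lay in band 5q31.3, on chromosome 5 from 140362663 to 140364959 in hg18. Its scores were 523 and 3100 in the H3122 replicates, 3100 in H1819 and 3137 in H2087, and FOXA1 had a peak there with a score of 1567. The next were in 15q26.1 (chromosome 15, 91147584 to 91149015) and 9q22.32 (chromosome 9, 98178662 to 98180204). Regions in 15q23, 2p16.1, 6p25.3, 15q25.1, 8p11.21, 1q25.3 and 17q25.1 completed the 10 highest, and FOXA1 had a peak in each of the 10. Among H1819 regions with no other NKX2-1 list, 3 were tied at the saturated score of 3100, in 1p21.2 (chromosome 1, 101220657 to 101221638), 1q41 and 7q31.1. In H2087, 3 were tied likewise, in 5q35.2 (chromosome 5, 174605078 to 174606916), 10q25.2 and 12p13.33. By mean rank over both H3122 replicates, the first region in no other line was in 5q31.3 (chromosome 5, 139510971 to 139512094), with scores of 656 and 2767; the other 4 of the 5 first scored higher in replicate 2. None of the 5 highest H1819 regions or the 5 highest H2087 regions had an H3122 FOXA1 peak, while all 5 of the H3122 regions did. These counts are near the shares of the classes. FOXA1 was in 6.08% of all regions of the H1819 list alone and 8.31% of those of the H2087 list alone. In the highest decile of replicate 2 scores it was in 92.75% of H3122-only regions and 89.5% of regions common to the 3 lines.

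FOXA1 and NKX2-1 occupied many of the same places in H3122. Of the replicate 2 NKX2-1 peaks, 22972 of 48061 on assembled chromosomes overlapped a FOXA1 peak, 47.8% (47.4 to 48.2), against 1.89% by chance, a 25.3-fold excess. Of the FOXA1 peaks, 54.5% (54.1 to 55.0) overlapped NKX2-1 replicate 2, 25.5-fold above chance. The overlap rose with score on both sides. It went from 26.7% to 83.7% between the lowest and highest deciles of NKX2-1 scores, and from 27.9% to 91.7% between those of FOXA1 scores. Replicate 1 gave a like share of its own peaks, 50.3% (49.1 to 51.4), with 36.1% in its lowest and 78.7% in its highest decile. With the 7469 best peaks of each list the shares were 21.7% for replicate 1 and 38.1% for replicate 2. That selection kept every replicate 1 peak but only the highest-scoring replicate 2 peaks. Since the overlap rose with score, the gap does not show that the replicates disagree. The share of FOXA1 peaks with NKX2-1 depended on the NKX2-1 list, and was 8.72% with the short replicate 1. FOXA1 was measured in H3122 only; 28.7% of H1819 and 31.6% of H2087 NKX2-1 peaks lay on an H3122 FOXA1 peak. With the 7469 best peaks of each list, 924 H1819 and 919 H2087 peaks did.

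**Figure D2:**
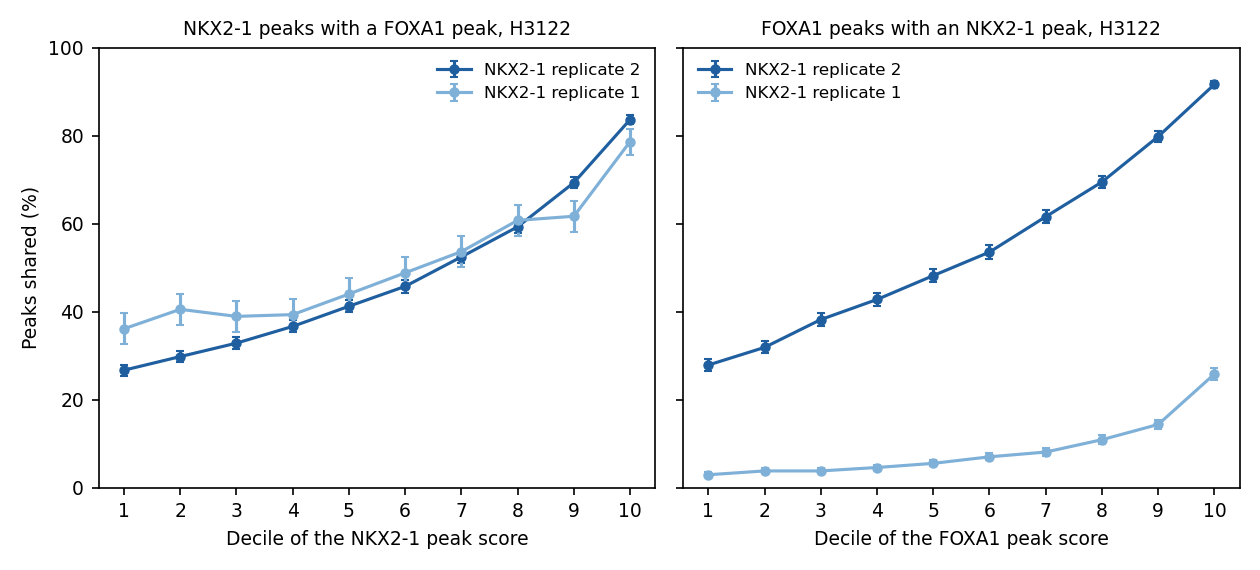
Share of H3122 peaks (%) that overlapped a peak of the other factor, by decile of the peak score, lowest to highest; bars are Wilson 95% intervals. Left, NKX2-1 peaks with a FOXA1 peak; right, FOXA1 peaks with an NKX2-1 peak. With replicate 2 the share rose from 26.7% to 83.7% on the left and from 27.9% to 91.7% on the right.

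By mean rank, the first region shared by NKX2-1 replicate 2 and FOXA1 was in 7p21.1 (chromosome 7, 17563824 to 17566237), with scores of 3210 and 3100. It also had NKX2-1 peaks in replicate 1, H1819 and H2087. Regions in 6q16.3, 1q24.3, 3p12.3 and 9q21.31 followed. Strong NKX2-1 binding without a FOXA1 peak also occurred, with 1q23.1 (chromosome 1, 155161887 to 155163184) first by mean rank. That region scored 665 and 3100 in the H3122 replicates, 780 in H1819 and 3100 in H2087. The strongest FOXA1 peak without NKX2-1 in H3122 was in 2q37.1 (chromosome 2, 231311494 to 231312570, score 2924). Another of the 5 highest was in 14q13.1 (chromosome 14, 34078188 to 34078924, score 2256), where H2087 had a low-scoring NKX2-1 peak (score 65.1).

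NKX2-1 regions common to the 3 lines carried FOXA1 less often than regions bound in H3122 only. FOXA1 was found in 55.7% (52.6 to 58.8) of the 962 common regions and in 64.0% (62.2 to 65.7) of the 2911 regions of both H3122 replicates alone. The difference was -8.25 percentage points (-11.8 to -4.67; Fisher's exact test over regions, p = 6.1e-06). Common regions had the higher NKX2-1 scores, with medians of 589 and 366 in replicate 2. With replicate 2 alone standing for H3122 the difference was smaller, at -3.61 points (-5.54 to -1.67). Within deciles of the replicate 2 score the difference widened to -18.2 points (-21.4 to -15.1, Cochran-Mantel-Haenszel chi-square test, p = 2.88e-30). This value is pooled over the deciles. In the highest decile the shares were closer, at 89.5% of 153 common regions and 92.75% of 207 H3122-only regions. Regions shared with H1819 alone had FOXA1 in 69.6%, which was 5.60 points above the H3122-only regions, but -5.18 points (-8.20 to -2.16) at matched scores. Regions shared with H2087 alone had it in 59.6%, a difference of -4.34 points (Fisher's exact p = 0.0102) that was -9.02 at matched scores. FOXA1 was rare in regions without an H3122 NKX2-1 peak, at 6.08% for H1819 alone and 8.31% for H2087 alone. It was also found in just 4.83% of the 1284 regions seen only in replicate 1, against 46.6% of the 31244 seen only in replicate 2.

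**Figure D3:**
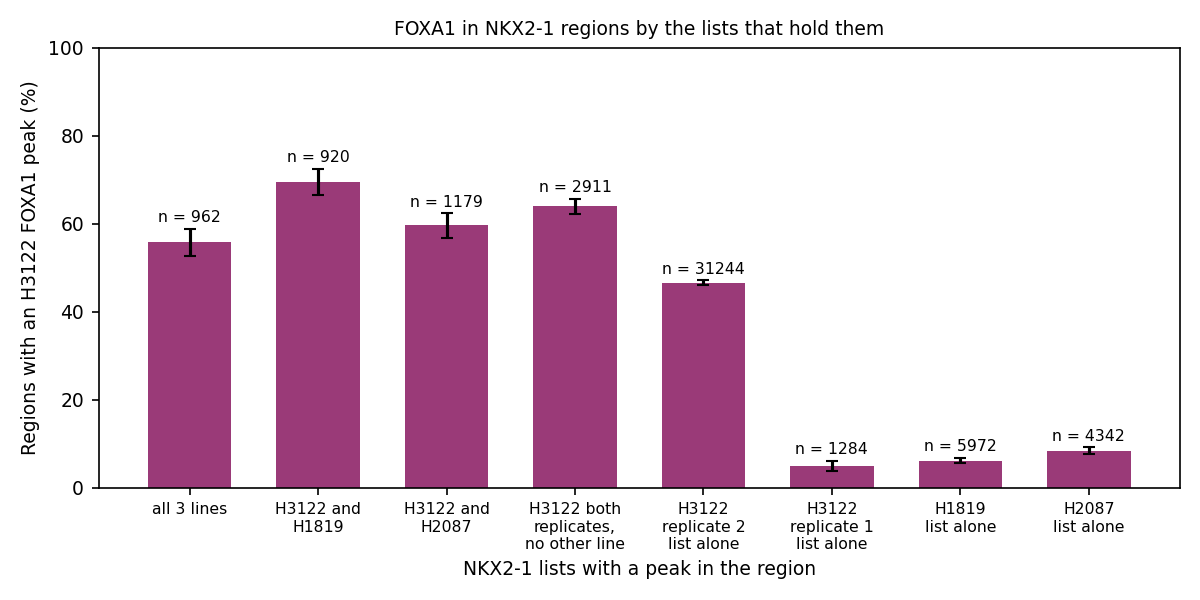
Share of merged NKX2-1 regions (%) with an H3122 FOXA1 peak, by the NKX2-1 lists that had a peak in the region; error bars are Wilson 95% intervals and n is the number of regions. The share was 55.7% in all 3 lines, 64.0% in both H3122 replicates and no other line, and 8.31% or lower in the H1819, H2087 and replicate 1 lists alone.

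The labels describe the lines as carrying an amplification of NKX2-1, which lies at 14q13. Band 14q13.3, from 35600001 to 36900000 on chromosome 14, held 10 and 50 NKX2-1 peaks in the H3122 replicates, 15 in H1819 and 11 in H2087, and 43 FOXA1 peaks. These were 3.17, 2.46, 2.64, 1.80 and 2.40 times the mean density of each list. Among 755 bands, these NKX2-1 densities stood at percentiles 98.7 and 98.9 in H3122, 96.6 in H1819 and 79.7 in H2087. One region in the band, from 35858859 to 35860048, had NKX2-1 peaks in all 4 lists and no FOXA1 peak, with scores of 117 and 510 in H3122, 233 in H1819 and 225 in H2087. Density was also raised in the adjacent 14q13.2, at 3.02, 1.67, 2.13 and 2.13 times the mean in the NKX2-1 lists. In 14q13.1 it was 1.25 and 1.31 times the mean in H3122, and below the mean in H1819 at 0.894 and in H2087 at 0.464. In 14q21.1, the band of FOXA1, it was 0.604, 0.797, 0.836 and 0.364 times the mean. Copy number was not measured in these lists.

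**Figure D4:**
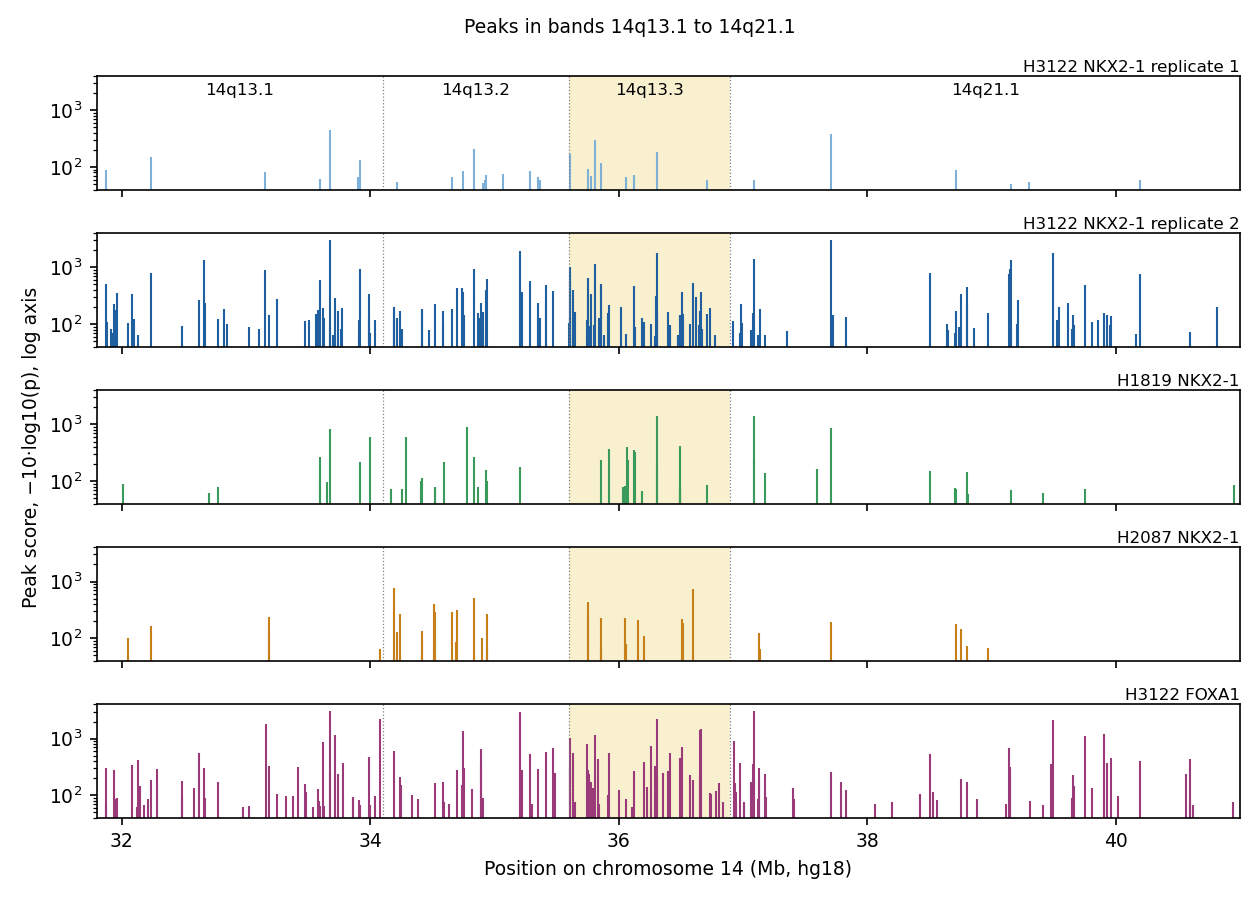
Peaks in bands 14q13.1 to 14q21.1, with position on chromosome 14 in Mb (hg18) on the horizontal axis and the authors' peak score on a log axis for each list; the shaded band is 14q13.3 and dotted lines are band borders. In 14q13.3 there were 10 and 50 NKX2-1 peaks in the H3122 replicates, 15 in H1819, 11 in H2087 and 43 FOXA1 peaks.

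Along the genome, NKX2-1 replicate 2 and FOXA1 had 4 of their 5 densest windows in common, and none of the 5 densest of H2087 was among those of another list. The window at 124 to 125 Mb of chromosome 5 (5q23.2) led both, with 75 NKX2-1 and 78 FOXA1 peaks, 4.81 and 5.66 times the mean. Windows in 12q21.33, 7p21.1 and 1p36.23 were among the 5 densest of both. The 1p36.23 window, 8 to 9 Mb on chromosome 1, was among the 5 densest in every list but that of H2087, which had 30 peaks there. H1819 was densest on the border of 12p13.1 and 12p13.2, with 31 peaks or 7.08 times the mean. H2087 was densest in 17p13.1, with 45 peaks or 9.60 times the mean, followed by 11q13.1 with 41. In windows of 500 kb the maxima of the NKX2-1 lists lay between 6.28 and 13.23 times the mean.

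The full NKX2-1 lists were denser in lightly than in darkly staining bands, most of all in H2087; this comparison was chosen after the data were seen. The density in unstained bands over that in the darkest was 3.64 (3.14 to 4.39, bootstrap over chromosomes) in H2087, 1.60 (1.37 to 1.86) in H1819, and 2.05 (1.82 to 2.35) and 1.38 (1.23 to 1.55) in H3122. For FOXA1 it was 1.02 (0.903 to 1.13). The 7469 best peaks of NKX2-1 replicate 2 had a ratio of 1.08 (0.934 to 1.24), an interval that includes 1 and overlaps the 0.943 (0.786 to 1.10) of the best FOXA1 peaks. In each NKX2-1 list the density was highest in the lightest stained class, at 1.65 times the autosomal mean in H2087, 1.45 in H1819, and 1.46 and 1.24 in H3122. Within chromosomes, the ratio of the unstained and lightest stained bands together over the 2 darkest classes was higher in H2087 than in H1819 on 20 of 20 chromosomes, with a median ratio of 1.80. In H3122, replicate 2 peaks without FOXA1 had a ratio of 1.83 (1.64 to 2.09), and those with FOXA1 one of 1.06 (0.927 to 1.19). Peaks with FOXA1 also scored higher (median 197 against 108), so a link to FOXA1 cannot be told apart from one to score.

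**Figure D5:**
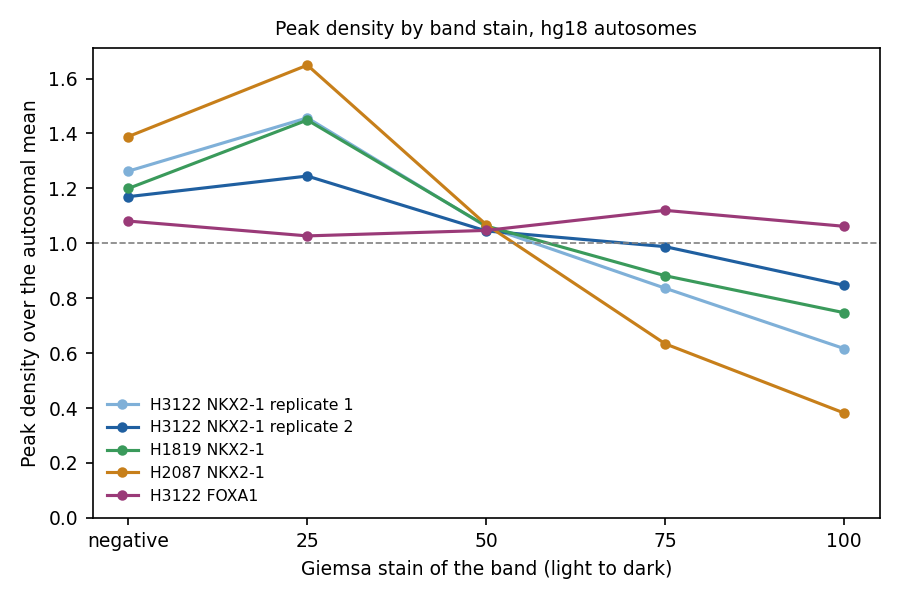
Peak density of each list relative to its autosomal mean (vertical axis) in bands of hg18 autosomes, ordered by Giemsa stain from unstained to darkest; each line is 1 list. H2087 was at 1.39 in unstained bands, highest at 1.65 in the lightest stained class and lowest at 0.382 in the darkest; FOXA1 was 1.08 in unstained and 1.06 in the darkest bands.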

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

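No test was run on the results of this part. Peaks on sequence that hg18 assigns to a chromosome without a position were left out of the comparisons. Their number passed the limit of 3 that a count of 0 allows in H3122 NKX2-1 replicate 2 with 10 peaks, in H2087 with 4 and in H3122 FOXA1 with 8. H1819 had 3 and replicate 1 had 0. The limit was not scaled to list length: the 3 flagged lists held 48071, 14441 and 42437 peaks, and H1819 held 13486. A count above the limit therefore does not set a library apart. Unplaced sequence of chromosome 17 held 4 of the replicate 2 peaks, 2 of the H2087 peaks and 3 of the FOXA1 peaks, and 1 H1819 peak with a score of 2043.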

How the results depend on the processing

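The score limit of 60, the stain classes, the midpoint and width rules for the FOXA1 comparison and the comparisons with 1 other line were chosen after the data were seen; the other alternatives were planned. Of 118 alternatives over 40 results, 63 were counted as unchanged, 54 moved the value and 1 reversed it. Unchanged meant within the interval of the value or, for differences in FOXA1 share, the same direction and side of the threshold. For numbers of peaks and regions, widths and covered lengths, which have no interval, it meant within a fixed ratio of the value. That ratio was wide: the fall of H2087 from 14441 to 9778 peaks at scores of at least 100 was counted as unchanged. The score limit of 60 removed no peak from any list but replicate 1. Results without replicate 1 could not change under it, and their unchanged counts say nothing about stability. Limiting the lists to autosomes removed few peaks, as in replicate 2 (48071 to 47027), so its 15 unchanged counts say little as well. The lower FOXA1 share of regions common to the 3 lines kept its direction and its side of the threshold in all 6 alternatives tried. Matching on score or width could hardly have weakened it, since common regions had higher scores and wider peaks. The midpoint rule takes away the advantage that wide regions have at a 1 bp overlap. It was thus also likely to widen the difference, and gave -13.08 points. The alternatives that could weaken it were replicate 2 standing for H3122 and the stain classes. The difference was smallest with replicate 2 standing for H3122, at 44.5% and 48.1%, or -3.61 points (-5.54 to -1.67). It was largest at -18.2 points at matched scores.

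The reversed result was the higher FOXA1 share of regions shared with H1819, 5.60 points, which became -5.18 at matched replicate 2 scores, since these regions had higher scores (medians 627 and 366). Scores of at least 100 left 1794, 31919, 8312 and 27852 peaks in replicate 1, replicate 2, H1819 and FOXA1, and 0.792 Mb covered in replicate 1. At that limit replicate 1 peaks were shared with replicate 2, H1819 and H2087 in 96.5%, 32.0% and 36.6% of cases. H1819 and H2087 peaks were shared with replicate 2 in 50.0% and 64.6%, and H1819 with H2087 in 20.4%. NKX2-1 was shared with FOXA1 in 46.6% and FOXA1 with NKX2-1 in 53.7%. The densest window of replicate 1 rose to 13.7 times the mean. A limit of 60 gave 85.2%, 27.4% and 31.6% for replicate 1 against replicate 2, H1819 and H2087.

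Midpoints within 200 bp gave 67.6%, 23.1% and 23.8% for those 3 pairs, 44.1% and 53.0% for H1819 and H2087 in replicate 2, 18.6% for H1819 in H2087, and 40.7% and 46.1% between NKX2-1 and FOXA1. An overlap of 50% of the shorter peak gave 66.3% for H2087 in replicate 2, 22.1% for H1819 in H2087, and 46.6% and 53.2% for NKX2-1 and FOXA1. The same number of best peaks gave 46.3%, 17.8% and 22.5% for replicate 1, 24.98% and 28.6% for H1819 and H2087 in replicate 2, and 18.1% for H1819 in H2087; shorter lists leave fewer peaks to meet. Local shifts lowered the fold above chance to 33.6, 46.0 and 36.7 for replicate 1 against replicate 2, H1819 and H2087, 19.5 and 20.4 for H1819 and H2087 in replicate 2, 24.98 for H1819 in H2087, and 18.6 and 18.6 for NKX2-1 and FOXA1.

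Regions common to the 3 lines numbered 2742 without replicate 1 and 951 without replicate 2, 2754 with either replicate and 290 at scores of at least 100. Without replicate 2 the FOXA1 share of NKX2-1 peaks was 50.3%, and NKX2-1 was on 8.72% of FOXA1 peaks. With replicate 2 peaks that overlap replicate 1 these were 62.4% and 9.14%. Windows of 500 kb gave maxima of 12.4, 6.28, 10.97 and 13.23 times the mean in replicate 1, replicate 2, H1819 and H2087. Apart from list length and score, the cause of these moves was not tested.

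No paired analysis was possible because the results come from single peak lists and only H3122 NKX2-1 has 2. Other settings for genes near peaks, gene lists and motifs were not run, for lack of an hg18 annotation and sequence here. The unknown depth limits any reading of peak numbers.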

Other observations

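The tests of low-scoring H2087 peaks and of H2087 peaks shared with H3122 were set before their results were seen; the other tests of this part, and the bands named for single genes, were chosen after. The bands given here are 1.7 Mb or longer, so their densities do not belong to the gene named; 4 of the 10 bands looked up are given here, and those of NKX2-1 and FOXA1 with the comparison of 14q13. The band of LMO3 (12p12.3), a LIM-only cofactor, had 1.54 and 1.66 times the mean NKX2-1 density in H3122 replicates 1 and 2, 1.43 in H1819 and 1.13 in H2087, and 1.95 times the mean for FOXA1. The band of ABCA3 (16p13.3), a lipid transporter of surfactant-producing cells, had 2.95 and 1.48 times the mean in H3122 replicates 1 and 2, 2.91 in H2087 and 0.580 in H1819. The band of SCGB1A1 (11q12.3), a secretory protein of airway club cells, had 1.70 and 1.73 in H3122, 3.51 in H2087 and 2.69 in H1819. The band of the surfactant protein gene SFTPB (2p11.2) was below the mean in every list, from 0.547 for FOXA1 to 0.906 in H2087.

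NKX2-1 replicate 2 in H3122 shared more of its best peaks with FOXA1 in the same line than with NKX2-1 in the other lines. In the 7469 best peaks of each list, the share was 38.1% (37.0 to 39.2) with FOXA1. It was 28.4% (27.4 to 29.5) with H2087 and 24.6% with H1819. All replicate 2 peaks against the 13483 best of each gave the same order with a smaller gap. Those shares were 22.6% (22.2 to 22.96), 19.2% (18.9 to 19.6) and 14.7%. Both cuts kept a smaller, higher-scoring part of the FOXA1 list (42429 peaks) than of the H2087 list (14437 peaks). Since overlap rose with score, equal numbers of peaks do not settle whether list length caused the order. For replicate 1 the 7469 best peaks gave 21.7% with FOXA1 and 22.5% with H2087, but 30.6% (29.6 to 31.7) and 29.1% (28.1 to 30.2) against the 13483 best peaks of each. Replicate 1 shared less with H1819 than with FOXA1 in both comparisons, at 17.8% (16.9 to 18.6) and 25.4% (24.45 to 26.4). The FOXA1 and H2087 shares went opposite ways with overlapping intervals, and the rule for reading them together was set after both were seen. A property of the replicate 2 and FOXA1 libraries cannot be told apart from one of H3122. No biological explanation was tested, and FOXA1 was not mapped in the other lines.

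Regions common to the 3 lines carried FOXA1 less often than H3122-only regions. Common regions lay more often in light bands, 67.6% against 58.7%, and the stain of the bands as the whole cause is argued against by -6.93 points within stain classes (-10.5 to -3.33). Score and width were matched but not weighed as causes. Common regions had the higher median score, 589 against 366 in replicate 2, and the wider replicate 2 peaks, 978 against 788 bp. FOXA1 was more frequent at higher scores, so matching could hardly narrow the difference. It was -18.2 points within score deciles, -17.85 (-21.98 to -13.72) within region width deciles and -14.28 (-17.96 to -10.6) within replicate 2 peak width deciles. Sequence content and distance to promoters stay open, since neither was measured. No biological explanation was tested: shared occupancy does not measure dependence of NKX2-1 on FOXA1, and FOXA1 was mapped in H3122 only.

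H2087 NKX2-1 peaks were concentrated in light bands more than those of the other lists. Whole-chromosome copy number is argued against by the higher ratio of the 2 lighter over the 2 darker classes than in H1819 within 20 of 20 chromosomes, and low-scoring peaks by a ratio of 3.66 at scores of at least 100, above the upper bound of 1.78 for H1819. Background of the H2087 library was not settled. H2087 peaks shared with H3122 replicate 2 had a ratio of 3.29 (2.84 to 3.96), above the 1.89 (1.60 to 2.23) of H1819 peaks shared in that way. Sharing cannot decide the question, because a bias of the H2087 library would also affect which shared sites it detects. Unshared H2087 peaks had a higher ratio of 4.58, while unshared H1819 peaks had a lower one of 1.35. GC bias of the library, segmental copy number and the share of promoters stay open. A difference between the cell lines also stays open, untested with 1 library each of H1819 and H2087.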
